A study of Arabidopsis thaliana with 4 samples.

How the data were processed

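Polyadenylated RNA from whole seedlings was measured in 4 libraries, 2 of WT and 2 of jmj28-3, and each value column was matched to its library by the labels, with 0 value columns left unmatched. The authors deposited FPKM, fragment counts scaled by transcript length and by the mapped fragments of the library, with 2 decimals and 1 column per library. Per the submitters' processing notes the tools were TopHat, RSEM and edgeR and the genome build was TAIR10, with no versions, settings or order. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be separated. Library sums of the deposited FPKM ran from 983897 to 991510, and the 10 genes with the highest values took 12.3% to 12.8% of each sum.

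FPKM hold no read counts, so no count model was used. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 on genes whose mean FPKM over the 4 libraries was at least 0.5. The linear model had genotype as its only term, and eBayes used a trend of the prior variance with mean level. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale and understate the change of genes with low values. Fold values are ratios of mean FPKM, and no fold is given against a genotype listed at 0. The adjusted p of each single gene comes from this limma fit.

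Lists of genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over 17 lists with at least 3 tested members. Camera with an estimated correlation called 0 of the 17 lists and camera with the preset correlation called 8. The estimated form also takes its degrees of freedom from the 4 libraries, so a list could hardly pass it. In the salicylic acid list, with an estimated correlation of -0.0122, the unadjusted p of camera still went from 0.046 to 0.169. Failing the estimated form therefore does not decide whether a list moved. The fry test, which asks only whether a list's genes move on balance one way, was run beside it. The tests, the 18 lists and the rule for named genes were fixed before the data were examined. The rule named JMJ28, CO, FT, SOC1, FLC and FBH1 to FBH4. It added the 10 largest rises and the 10 largest falls among called genes with both jmj28-3 libraries on the same side of both WT libraries. From each list it took up to 4 called members with the largest change, or the 2 members with the smallest p where none was called. TEM1, CDF5, CDF3, TOE1, TCH2, WRKY33, WRKY40, CML38, LHY, PRR7, RVE4, DREB2A, RD26, RD29B, DFR and LDOX fall outside the rule and were named after their values were seen, as were single genes of families, of the B-box class and of the added lists in the closing section.

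Relative depth was read from the most frequent ratio between libraries of FPKM values from 0.2 to 1, which works because few reads give values in steps. Absolute depth is unknown, so no counting interval is given. The limma step was tested on simulated data for jmj28-3 against WT, with 20232 genes and 200 changed genes in each of 5 runs. It recovered 26.9% of genes changed 1.5-fold, 61.5% of those changed 2-fold and 85.8% of those changed 4-fold. There were 3.4 false calls per run among 119.2 calls on average. Changes were added on the log2(FPKM + 1) scale, leaving out genes with low values, and noise was normal and independent between genes. The data gave 1613 calls, so recovery and false calls there may differ.

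Gene symbols and positions came from the RefSeq annotation of TAIR10.1, in which 32835 of the 33602 identifiers were found. The table carries no coordinates, and positions were taken by gene identifier. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum mean FPKM of 2, median-of-ratios scaling, quantile normalization, rescaling each library to the same sum (TPM), replicate number as a block, no variance trend, and leaving out each library. A few genes are not reported here.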

Results

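The series compared seedlings of Arabidopsis thaliana that were wild type (WT, accession Col-0) with seedlings of the jmj28-3 line. JMJ28 is annotated as a protein with a RING-type zinc finger and a jumonji domain, the domain of histone demethylases. Whole seedlings aged 12 days and grown in long days gave polyadenylated RNA for 4 sequencing libraries, 2 per genotype. The deposited values were FPKM for 33602 genes, of which 9363 were listed at 0 in all 4 libraries. Between 22645 and 22863 genes had a value above 0 in a library, and between 18970 and 19155 reached an FPKM of 1. The number of reads per library was not given in the sources used here. The steps between low FPKM values put the depth of WT replicate 2, jmj28-3 replicate 1 and jmj28-3 replicate 2 at 1.08, 1.18 and 0.996 times that of WT replicate 1. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

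JMJ28 itself (AT4G21430) was transcribed in all 4 libraries. Its FPKM was 3.80 and 5.54 in WT and 3.65 and 3.33 in jmj28-3, a log2 change of -0.32 (SE 0.172, adjusted p = 0.327). The difference was not larger than the spread between replicates. The gene lies on chromosome 4 at 11407804 to 11412279 of TAIR10.1, on the minus strand, with 1 annotated mRNA of 12 exons. The kind of lesion in jmj28-3 is not given in the labels, so the transcript level does not check the genotype of the libraries.

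The 2 genotypes separated clearly. Pearson correlations of log2(FPKM + 1) were 0.989 within WT and 0.989 within jmj28-3, and 0.977 to 0.981 between genotypes. The first principal component held 60.4% of the variance and placed WT at -25.2 and -23.9 and jmj28-3 at 22.1 and 27.0. Values of the 2 genotypes did not overlap for 55.2% of tested genes, where chance gives 33.3%.

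Of 20232 tested genes, 846 were higher and 767 were lower in jmj28-3 at an adjusted p under 0.05 in limma. Large changes were mostly rises, with 243 genes higher by at least 1 log2 unit and 86 lower by as much. Among the largest rises, BT2 (AT3G48360), a BTB and TAZ domain protein, went from 7.36 ± 3.44 to 116 ± 8.98 FPKM (SD, n = 2), a log2 change of 3.86. The touch-induced xyloglucan endotransglucosylase/hydrolase TCH4 (AT5G57560) went from 28.4 ± 5.47 to 306 ± 15.1 FPKM, 10.8-fold. PHI-1 (AT1G35140), of the phosphate-responsive family, rose 8.45-fold. AT3G15450, annotated as aluminium induced, rose 7.70-fold, from 39.86 and 87.17 FPKM in WT to 476.3 and 501.72 in jmj28-3. The alpha/beta-hydrolase gene AT1G02660 rose 9.52-fold. AT1G50040 rose 14.9-fold, from low values of 1.15 and 0.35 FPKM in WT to 10.06 and 12.35 in jmj28-3. AT4G32480 rose 6.69-fold, from 8.92 and 17.11 FPKM to 80.67 and 93.53. The other 3 genes with the largest rises were listed at 0 in both WT libraries. These were the small nucleolar RNA SNOR77 (AT5G10572) with 17.2 and 25.1 FPKM in jmj28-3, the metallothionein gene MT1B (AT5G56795) with 11.4 and 7.72, and AT2G36030 with 6.26 and 10.1. Reads of MT1B can be shared with related metallothionein genes, so its values are uncertain. Genes listed at 0 in both libraries of a pair and at an FPKM of at least 1 in both of the other numbered 5 for the genotypes, and 7 and 17 for the other 2 ways of pairing the libraries. At that level such genes were no more frequent between genotypes than between other pairs. The counts do not cover how far above 1 FPKM the values lie, so they do not settle these 3 rises.

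The largest falls included 4 genes for small B-box proteins, a family with roles in light responses that also has members that rose. BBX32 (AT3G21150) went from 11.8 ± 1.90 to 0.955 ± 0.926 FPKM (SD, n = 2) and was 12.4-fold lower in jmj28-3. BBX30 (AT4G15248) was 9.52-fold lower, BBX31 (AT3G21890) 4.97-fold and BBX29 (AT5G54470) 5.15-fold. The receptor kinase gene AT1G29720 was 10.6-fold lower, and AT3G09450, AT2G15020 and the defensin-like gene AT5G33355 were 11.5-fold, 6.60-fold and 5.85-fold lower. The folds of AT1G29720 and AT3G09450 rest on low values in jmj28-3, of 0.51 and 0.69 FPKM and of 0.38 and 0.39 FPKM. The microRNA gene MIR163 (AT1G66725) was 5.62-fold lower, at 13.2 and 14.2 FPKM in WT and 3.98 and 0.89 in jmj28-3. The SKP1-like gene SK4 (AT1G20140) was 4.79-fold lower. Adjusted p in limma for the 20 genes with the largest changes ran from 0.000544 for AT1G02660 to 0.0387 for MIR163.

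**Figure D1:**
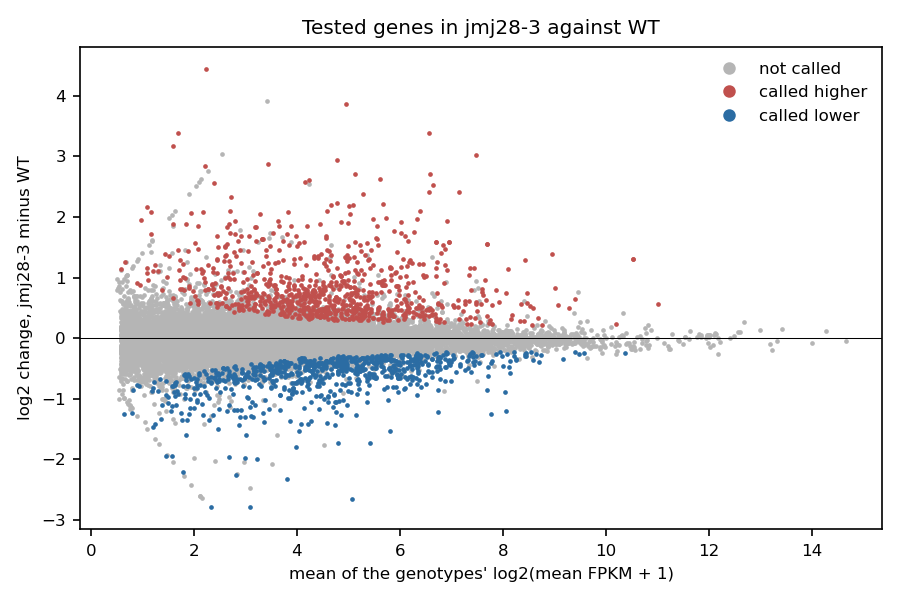
Each point is a tested gene, with the mean of the genotypes' log2(mean FPKM + 1) on the horizontal axis and the log2 change of jmj28-3 minus WT on the vertical axis. Genes called higher (846 in the fit) are red and those called lower (767 in the fit) are blue, and changes above 1 log2 unit are mostly rises. The few genes that are not reported here are not drawn.

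The counts fell whenever a library was left out, which leaves 3 libraries and 1 residual degree of freedom. Leaving out jmj28-3 replicate 2 left 70 genes higher and 21 lower, leaving out jmj28-3 replicate 1 left 215 and 123, leaving out WT replicate 1 left 341 and 164, and leaving out WT replicate 2 left 398 and 156. Testing every gene above 0 gave 526 and 351, a fit with no variance trend 469 and 287. Over 54 called genes named by the fixed rule, the largest shift of the log2 change in a leave-out was 11.1% of the change at the median and 31.0% at most, and 0 changed sign. Lost calls were not tested for dependence on a single library as against the lower power of such fits. All 4 leave-outs kept the calls on SNOR77, TCH4, MT1B, AT2G36030, PHI-1, AT1G02660, BBX30, AT2G15020, AT1G29720, SK4 and BBX29. Without jmj28-3 replicate 2 the adjusted p was 0.0644 for BT2, 0.0768 for AT1G50040 and 0.0616 for AT5G33355. The calls on AT3G15450, AT4G32480, BBX31 and AT3G09450 were lost without either jmj28-3 library, with adjusted p up to 0.115, 0.0992, 0.0744 and 0.0763. Those on BBX32 and MIR163 were lost without either WT library, with adjusted p up to 0.0804 and 0.173. MIR163 was also not called with a pseudocount of 0.1.

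The comparison asks how flowering-time genes differ in jmj28-3, since JMJ28 is known as a regulator of CO that acts with FBH factors. The floral repressor FLC (AT5G10140), a MADS-box protein, went from 2.56 ± 0.290 to 12.5 ± 0.106 FPKM (SD, n = 2), 4.91-fold higher in jmj28-3 (log2 change 1.93, SE 0.104, adjusted p = 0.00186). SOC1 (AT2G45660), a MADS-box promoter of flowering, fell from 20.7 ± 2.1 to 12.0 ± 1.05 FPKM (log2 change -0.74, SE 0.103, adjusted p = 0.0166). FT (AT1G65480), the mobile flowering signal, had 1.24 and 1.08 FPKM in WT and 0.40 and 0.63 in jmj28-3, which did not pass (log2 change -0.51, adjusted p = 0.141). CO (AT5G15840), the photoperiod regulator upstream of FT, had 0.53 and 0.50 FPKM in WT and 0.99 and 0.50 in jmj28-3 (adjusted p = 0.628). CO lay near the minimum mean of 0.5 FPKM for a test, so its values neither show nor exclude a change. None of FBH1 to FBH4, bHLH activators of CO, was called, with log2 changes of -0.02, -0.35, -0.04 and 0.09 and adjusted p from 0.160 for FBH2 to 0.931 for FBH1.

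Of 20 tested floral repressors, 6 were higher, 2 were lower and 12 were not called. Besides FLC, its relatives MAF4 and MAF5 were higher by 1.28 and 1.09 log2 units and the AP2/B3 repressor TEM2 by 1.15. TEM1 and CDF5 were also higher, while CDF3 and TOE1 were lower. Adjusted over the list alone, 6 were higher and 3 lower. The list as a whole was higher by camera with the preset correlation (adjusted p = 0.0326), and not with an estimated correlation (adjusted p = 0.536). Of 16 tested photoperiod and flowering promoters, SPL3 was higher by 0.69 log2 units (adjusted p = 0.0366), SOC1 and SPL9 were lower, SPL9 by -0.65 (adjusted p = 0.044), and 13 were not called. Adjusted over the list alone these counts were 1 and 2, and the list did not pass camera (adjusted p = 0.407). MAF4 and MAF5 are tandem relatives, and reads can be shared between them. The hour of harvest is not given in the sources used here. For members that cycle over the day, such as the cycling DOF factor gene CDF3, these values do not separate genotype from hour. Leaving out any 1 library ended the calls on SOC1, SPL3 and SPL9, with adjusted p up to 0.149, 0.218 and 0.217. Without jmj28-3 replicate 2 the adjusted p of FLC was 0.0501, and those of MAF4, MAF5 and TEM2 rose to at most 0.152, 0.242 and 0.213, with calls lost without either jmj28-3 library and, for MAF4 and MAF5, without WT replicate 1. Quantile normalization also ended the call on TEM2.

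**Figure D2:**
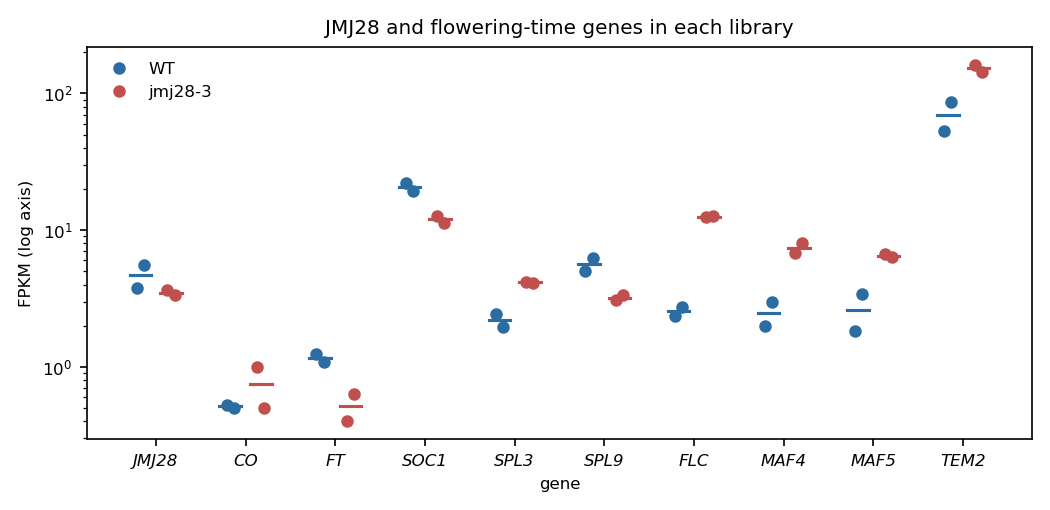
FPKM on a log axis for JMJ28 and 9 flowering-time genes, with a point per library (2 WT in blue, 2 jmj28-3 in red) and a line at each genotype's mean. FLC sits at 2.35 and 2.76 in WT and at 12.5 and 12.6 in jmj28-3, while the JMJ28 points of the genotypes lie close together.

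Of 10 tested clock genes that peak in the morning, 3 were lower and none was higher, with 6 lower when adjusted over the list alone. PRR9, a pseudo-response regulator, went from 29.4 ± 0.488 to 10.4 ± 0.948 FPKM (SD, n = 2), 2.82-fold lower (adjusted p = 0.00235). CCA1 and RVE6, MYB-type clock factors, were lower by 1.46-fold and 1.61-fold. LHY did not pass, at 71.4 and 72.6 FPKM in WT and 56.0 and 44.3 in jmj28-3 (adjusted p = 0.0534), and PRR7 and RVE4 had log2 changes of 0.12 and 0.14, also not called. LHY passed at a minimum mean of 2 FPKM (adjusted p = 0.043) and without jmj28-3 replicate 1 (adjusted p = 0.0422), with a range of 0.0157 to 0.199 over its alternatives. The list was lower by camera with the preset correlation (adjusted p = 0.00402), and not with an estimated correlation (adjusted p = 0.518). Of 7 tested evening-phased genes, CHE, a TCP factor, rose 1.96-fold (adjusted p = 0.00303) and the other 6 were not called, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.110). The hour of harvest is not given in the sources used here, and clock transcripts follow it, so these values do not separate genotype from hour. All 4 leave-outs kept the PRR9 call. Adjusted p rose to 0.0506 for CHE without jmj28-3 replicate 2, and to at most 0.131 for CCA1 and 0.152 for RVE6, whose call was lost in every leave-out.

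None of the 16 tested genes for JmjC proteins passed limma, over all genes or when adjusted over the list alone. The smallest p in that list belonged to JMJ24, with 16.9 and 16.5 FPKM in WT and 19.8 and 20.1 in jmj28-3 (adjusted p = 0.0958), and JMJ29 (adjusted p = 0.211). The median of the JmjC list was below 0, the direction given by camera was up, and the list did not pass (adjusted p = 0.793). None of 10 tested genes for H3K9 and DNA methylation passed either, and the smallest p were those of the demethylase gene DME and the methyltransferase gene KYP (adjusted p = 0.156 and 0.329, camera adjusted p = 0.159 for the list).

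Of 16 tested genes of the rapid response to touch and stress, 8 were higher, none was lower, 8 were not called, and 11 were higher when adjusted over the list alone. The calmodulin-like gene TCH3 rose from 36.5 ± 6.34 to 243 ± 30.1 FPKM (SD, n = 2), 6.67-fold. The ethylene response factor genes ERF104 and ERF6 rose 4.71-fold and 3.51-fold, and TCH2, WRKY33, WRKY40 and CML38 were also higher. DREB2A, not called, had a log2 change of -0.47. The list was higher by camera with the preset correlation (adjusted p = 2.58e-10), and not with an estimated correlation (adjusted p = 0.518). Whether the genotypes were handled alike at harvest was not tested, so the values of this touch and stress list do not separate genotype from handling. In the salicylic acid defence list, 3 of 13 tested genes were higher, both over all genes and when adjusted over the list alone. These were WRKY70 with 3.93-fold, CBP60g with 3.08-fold and WRKY18 with 2.28-fold, and the list did not pass camera (adjusted p = 0.0782). In the jasmonate list, the lipoxygenase gene LOX4 rose 3.37-fold, 14 of 15 tested genes were not called, and 2 were higher when adjusted over the list alone. In the heat shock list, the heat shock factor gene HSFA7A rose 2.33-fold, and 9 of 10 tested genes were not called, with 1 higher when adjusted over the list alone. Camera called both lists higher with the preset correlation (adjusted p = 0.00667 for jasmonate and 0.0158 for heat shock), and neither with an estimated correlation (adjusted p = 0.518 and 0.536).

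The calls on TCH3 and TCH4 held without any 1 library. Those on ERF104, WRKY18, CBP60g and LOX4 were lost in each leave-out, with adjusted p up to 0.144, 0.194, 0.126 and 0.0755. Those on ERF6 and WRKY70 were lost without either jmj28-3 library, with adjusted p up to 0.0978 and 0.140, and that on HSFA7A without either WT library or jmj28-3 replicate 2, with adjusted p up to 0.103.

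Of 18 tested cold and abscisic acid genes, 4 were lower, none was higher and 14 were not called, with 9 lower when adjusted over the list alone. The 4 were the dehydrin genes LTI30 and COR47, the cold-induced KIN2, and P5CS1, for an enzyme of proline synthesis, with log2 changes of -0.58, -0.27, -0.47 and -0.42. Among those not called, RD26 had a log2 change of 0.67 and RD29B of -1.40, and RD29B passed without WT replicate 1 (adjusted p = 0.0337, from 0.016 to 0.348 over its alternatives). COR47 was not called with median-of-ratios scaling. Camera called the list lower with the preset correlation (adjusted p = 0.000313), and not with an estimated correlation (adjusted p = 0.518). Of 16 tested flavonoid genes, 6 were lower, none was higher and 10 were not called, with 8 lower when adjusted over the list alone. The flavonol regulators MYB12 and MYB111 were lower by 2.58-fold and 2.13-fold, the flavonol synthase gene FLS1 went from 104 ± 2.27 to 61.0 ± 1.56 FPKM (SD, n = 2), and the chalcone isomerase gene TT5 was 1.54-fold lower. The later anthocyanin genes DFR and LDOX, not called, had log2 changes of 0.72 and 0.21. DFR passed without WT replicate 2 (adjusted p = 0.0114, up to 0.541 over its alternatives), and LDOX was at -0.33 without WT replicate 1. Camera called the flavonoid list lower with the preset correlation (adjusted p = 0.00205), and not with an estimated correlation (adjusted p = 0.536).

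In the glucosinolate list, 5 of 16 tested genes were lower and 1 was higher, and adjusted over the list alone 7 were lower and 2 higher. MYB28 and MYB29, regulators of aliphatic glucosinolates, were lower by 1.53-fold and 1.84-fold, and MYB34, a regulator of indolic glucosinolates, by 1.70-fold. MYB51, another regulator of indolic glucosinolates, went the other way, from 2.06 ± 0.120 to 8.84 ± 0.212 FPKM (SD, n = 2), 4.30-fold. Camera did not call the list (adjusted p = 0.0526). In the iron list, 1 of 19 tested genes was called, over all genes and adjusted over the list alone, the peptide gene IMA3, which was 1.58-fold lower, and the list did not pass camera (adjusted p = 0.504).

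Leaving out jmj28-3 replicate 2 ended the calls on MYB51 (adjusted p = 0.0556) and FLS1 (adjusted p = 0.0559). The calls on KIN2, P5CS1, COR47, MYB12 and MYB111 were lost in each leave-out, with adjusted p up to 0.0748, 0.191, 0.185, 0.1 and 0.148. Those on LTI30, TT5, IMA3, MYB28, MYB29 and MYB34 were lost in at least 1, with adjusted p up to 0.0810, 0.0644, 0.0744, 0.0842, 0.154 and 0.0744.

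None of 22 tested nuclear genes for photosynthesis was called by limma, over all genes or adjusted over the list alone. LHCB1.2, for a light-harvesting protein, had 5760 and 6264 FPKM in WT and 7503 and 6952 in jmj28-3 (adjusted p = 0.0709), and RBCS1B, for a small subunit of Rubisco, had 5459 and 4772 in WT and 4318 and 4194 in jmj28-3 (adjusted p = 0.0955). At a minimum mean of 2 FPKM LHCB1.2 passed (adjusted p = 0.0478, from 0.00519 to 0.509 over its alternatives). Both belong to families of near-identical genes, so their values are uncertain. The list did not pass camera (adjusted p = 0.240). Transcripts encoded in the chloroplast made up 0.0687% and 0.0711% of summed FPKM in WT and 0.213% and 0.146% in jmj28-3. Mitochondrial transcripts made up 0.0041% and 0.00416% in WT and 0.00704% and 0.00964% in jmj28-3. These shares are given as values, since an exact permutation test of 2 libraries against 2 cannot go below p = 0.33. Gene by gene, limma called 7 organelle genes higher and 0 lower, all in the chloroplast, and these 7 held 4 distinct sets of values because some copies have identical values. The shares of both organelles differed with genotype, so they cannot be separated from it in any call made here. Differences in RNA quality or in the selection of polyadenylated RNA can move such shares, and neither was tested. Leaving out organelle genes gave 852 genes higher and 776 lower, an alternative chosen after seeing the data.

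Of 18 tested root markers, the cell wall protein gene PRP3 was 1.59-fold lower (adjusted p = 0.0119) and SCR, a regulator of the endodermis, 1.31-fold lower (adjusted p = 0.0364), 16 were not called, and 10 were lower when adjusted over the list alone. Camera called the list lower with the preset correlation (adjusted p = 0.00277), and not with an estimated correlation (adjusted p = 0.518). PRP3 lost its call without either jmj28-3 library and SCR in each leave-out, with adjusted p up to 0.132 and 0.219. Of 9 markers of the shoot apex and floral organs, 3 were tested and none was called, over all genes or adjusted over the list alone. KNAT1 had 6.53 and 7.04 FPKM in WT and 5.84 and 6.37 in jmj28-3 (adjusted p = 0.477), and SEP1 had 0.60 and 0.75 in WT and 0.24 and 0.45 in jmj28-3 (adjusted p = 0.359, camera adjusted p = 0.722 for the list). None of 13 seed storage and maturation genes reached the level needed for a test.

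**Figure D3:**
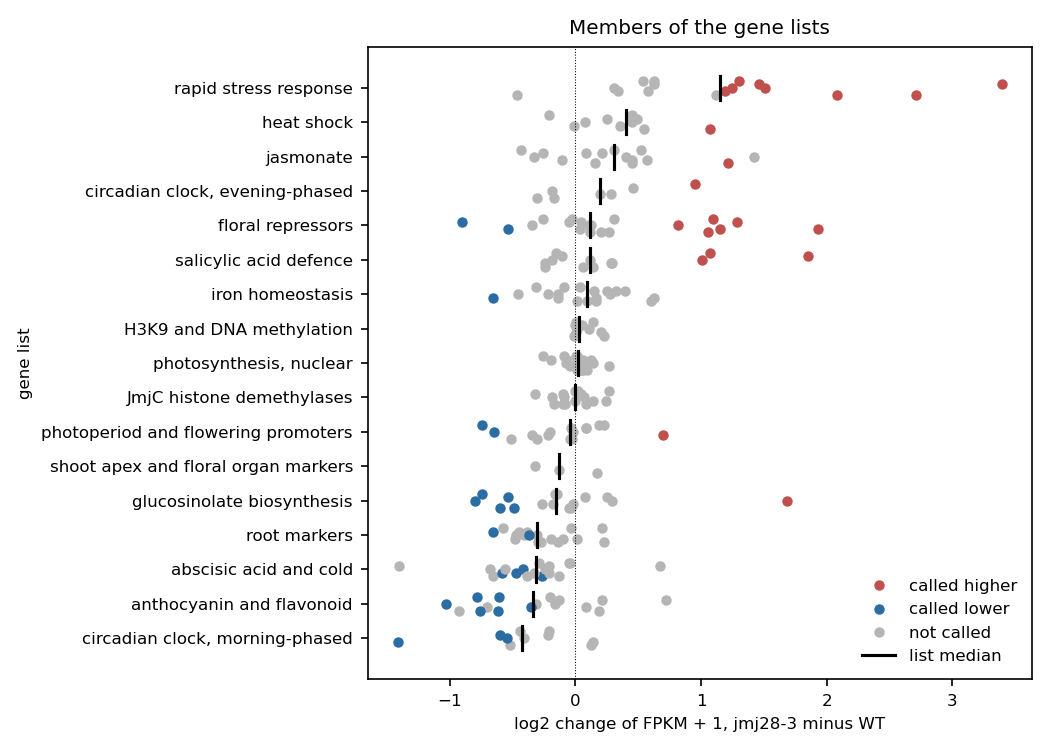
Log2 change of FPKM + 1 in jmj28-3 minus WT for the tested members of 17 gene lists, with a point per gene (red called higher, blue called lower, grey not called) and a black line at each list's median. The rapid stress list has the highest median, at 1.15, and the morning-phased clock list the lowest, at -0.42.

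A higher share of changed genes around JMJ28 did not pass the test. Within 2 Mb of the gene on chromosome 4 of TAIR10.1, 73 of 783 tested genes were called (9.32%), against 1529 of 19307 elsewhere (7.92%). The odds ratio was 1.2, with a 95% interval of 0.921 to 1.53 (Fisher's exact test, two-sided, p = 0.157). With no variance trend the odds ratio was 1.41 (Fisher's exact test, p = 0.0434), and without jmj28-3 replicate 2 it was 0.299 (p = 0.384).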

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

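The crossed pairing, the fit without organelle genes and the alternatives for the genes near JMJ28 were chosen after seeing the data, and the other alternatives before. Of 54 called genes named by the fixed rule, 0 changed sign under any alternative, 39 kept their call in all settings other than leave-outs, and 13 kept it in those and all 4 leave-outs. The 15 that lost it outside the leave-outs, with adjusted p up to 0.14, were MIR163, SPL3, SPL9, TEM2, MAF5, RVE6, CCA1, WRKY18, ERF104, KIN2, P5CS1, COR47, HSFA7A, MYB111 and SCR, and no filter, the block or the fit with no variance trend was among the settings for each. Of 23 called genes named after their values were seen, 0 changed sign, 19 kept their call outside the leave-outs and 3 in all 4 leave-outs. TEM1, CML38, AT2G20670 and AT3G54580 lost it outside them. BBX24 and BBX25, also called and named after their values were seen, were not among the 23. Leaving out 1 library at a time, which assumes that the lone library varies like the other genotype, gave 70 to 398 genes higher and 21 to 164 lower, with 3 libraries in each fit. The odds ratio for genes near JMJ28 ran from 0.299 to 1.23 in these fits. Genes above 0 in any library, with no filter, gave 526 higher and 351 lower. With no variance trend 469 were higher and 287 lower, and the odds ratio near JMJ28 was 1.41. Pseudocounts of 0.1 and 0.5, the minimum of 2 FPKM, both scalings, quantile normalization and the fit without organelle genes gave 783 to 956 genes higher and 617 to 852 lower. With median-of-ratios scaling 956 were higher and 617 lower, so 60.8% of calls were higher, against 52.4% in the main fit. The cause of this and the other shifts was not tested.

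With replicate number as a block, 534 genes were higher and 328 lower, 518 and 313 of them among the genes called without it. The numbers do not pair the libraries by their labels, and the correlation across genes of the replicate differences in WT and jmj28-3 was -0.133. Pairing the numbers crosswise gave 1158 higher and 1129 lower, and called 5 named genes that were not called with no block, FBH2, LHCB1.2, RBCS1B, LHY and RD29B. Grouping libraries by replicate number, or crosswise, limma called 0 genes. At an unadjusted p under 0.05 limma gave 185 and 343 genes, against 4903 for genotype. Each group of these other splits mixes WT and jmj28-3, so genotype differences widen the spread within groups. Low counts were therefore to be had in advance and are no control for the genotype count. The 3 splits are also too few for a share under 0.05.

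With an estimated correlation the adjusted p of camera was 0.518 for the morning clock, jasmonate, rapid stress, abscisic acid and cold, and root lists, and 0.536 for the floral repressor, heat shock and flavonoid lists. With 4 libraries a list could hardly pass camera with an estimated correlation, so these values do not decide whether a list moved. By fry, 6 lists moved on balance one way at an unadjusted p under 0.05. Of these the morning clock, rapid stress and root lists were called by camera, and the flowering promoter, evening clock and glucosinolate lists were not. The floral repressor, jasmonate, cold, heat shock and flavonoid lists, called by camera, did not pass fry. Median-of-ratios scaling called the glucosinolate list lower (adjusted p = 0.0491). Among genes that were not called, the log2 change of FBH1 was 0.012 with median-of-ratios scaling, against -0.019 without. In leave-outs it ran from -0.134 to 0.096 for FBH1, from -0.132 to 0.060 for FBH3 from -0.014 to 0.394 for CO and from -0.327 to 0.747 for LDOX. Fewer libraries entered these fits, and the cause of the sign changes was not tested. Tests on counts were not run because the table holds FPKM. Depth is known only relative to WT replicate 1, so no limit for genes listed at 0 is given.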

Other observations

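The tests of gene families by their deposited description, of transposable element genes, the count of B-box genes, and of root tissue as the whole cause of the hair gene difference were chosen only after the result was seen. Among 278 families with at least 8 tested genes, AP2/ERF factors, described as integrase-type DNA-binding proteins, were called higher more often than other genes. Of 52 tested members 11 were higher and 4 lower (odds ratio 6.21, Fisher's exact test, adjusted p = 0.00223). DREB26 (AT1G21910) went from a mean of 6.61 to 45.2 FPKM, AT5G61590 from 39.9 to 157, and ORA47 (AT1G74930) from 0.595 to 4.71. In the DUF506 family 5 of 10 tested genes were higher (odds ratio 23.0, Fisher's exact test, adjusted p = 0.00371), among them AT2G20670, from 62.9 to 316 FPKM.

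Of 70 tested UDP-glycosyltransferase genes, 11 were lower and 0 higher (odds ratio 4.78, Fisher's exact test, adjusted p = 0.0169). HYR1 (AT3G21760) went from 30.2 to 11.1 FPKM, UGT84A2 (AT3G21560) from 37.4 to 21.8 and AT1G06000 from 70.5 to 39.7. Of 10 extensin-like genes with proline-rich repeats, which encode cell wall proteins, 4 were lower and 1 higher (Fisher's exact test, adjusted p = 0.0332), among them AT3G54580, from 113.7 to 77.1 FPKM. In the DUF581 family 5 of 17 tested genes were lower and 1 higher (odds ratio 10.6, Fisher's exact test, adjusted p = 0.0332). Members of such families share sequence, and their single values are less certain than those of other genes. Of 3900 listed transposable element genes, only 105 reached the level needed for a test, so the result does not cover the others. Of these 105, 1 was higher and 5 lower, against 4.20% of other genes higher (Fisher's exact test, p = 0.136).

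Genes known from sugar depletion and touch stood among the largest rises in jmj28-3, and BBX29 to BBX32 among the largest falls. These were noticed there. By their description 19 B-box genes were tested, these 4 included, and 8 were lower, 3 higher and 8 not called. Of the 10 without a CCT domain 8 were lower and 1 higher, BBX27. Of the 9 with one 0 were lower and 2 higher, BBX14 and BBX17, so the class did not fall as a whole. An excess of higher calls among these 9 over all other tested genes did not pass (odds ratio 6.56, Fisher's exact test, p = 0.0517, adjusted p = 0.599 over 278 families). B-box genes with and without a CCT domain were not tested against each other. A candidate explanation is that the jmj28-3 seedlings were collected at an earlier or darker point of the day, which would move light-induced and sugar-depletion genes in opposite directions. No prediction was made from it for the touch genes. A pair of lists of light-induced and sugar-depletion genes was written after the pattern but before their values were examined. The median log2 change was -0.324 for 17 light and UV-B induced genes (8 lower, 0 higher, 9 not called). For 18 genes induced by sugar depletion and darkness it was 0.563 (10 higher, 0 lower, 8 not called). The light list is not independent of the pattern, since it holds BBX22, BBX24 and BBX25. BBX24 and BBX25 were called lower and BBX22 was not called, and BBX24 is also among the 8 lower B-box genes above. HYH went from 85.7 and 84.6 FPKM in WT to 55.0 and 53.7, and BZIP1 from 4.02 and 5.37 to 15.9 and 17.1, while the light-induced RPT2 was at 252.5 and 249.1 in WT and 276.3 and 262.1 in jmj28-3. Camera called both lists with the preset correlation, adjusted over the 4 lists added here (adjusted p = 8.92e-05 for light and UV-B and 1.74e-10 for sugar depletion), and neither with an estimated correlation (adjusted p = 0.225 for both). The hour of harvest is not given in the sources used here, and an effect of the genotype on the same genes stays open, untested. The same doubt holds for the clock genes of the report, whose transcripts follow the hour directly and were not tested against it. Flowering genes that cycle over the day were not tested against the hour either.

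Hair genes among the root markers lay below 0 in jmj28-3. Over 10 further root hair genes, written down before their values were examined, the median log2 change was -0.558, with all 10 below 0 and 2 called lower. Camera called this list and that of other root genes lower with the preset correlation (adjusted p = 4.89e-05 and 0.00754), and neither with an estimated correlation (adjusted p = 0.225 and 0.36). A smaller share of root tissue in the jmj28-3 libraries was taken to lower all root genes alike, a premise that was not tested. The median of 16 other root genes was -0.179, with 2 called lower, which lies between the values set beforehand for and against that explanation. The medians differed by 0.379 (SE 0.089, from resampling genes). That SE treats genes as independent and leaves out the spread between libraries. Hair genes also differed between the WT libraries, such as RHS13 with 66.3 and 99.2 FPKM, while PIP5K3 had 1.83 and 1.65. The difference therefore does not decide whether a smaller root share was the whole cause. The most abundant of these root genes, PYK10, had 1221 and 1183 FPKM in WT and 1178 and 1128 in jmj28-3. A smaller contribution of root tissue cannot be told apart from a change in root genes, since the share of roots was not measured, and an effect of the genotype on hairs was not tested.

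Some genes were listed at 0 in both libraries of one genotype and had a value in both of the other. Chance assignment of reads to short or duplicated genes in single libraries would give as many for other pairs of libraries. The genotypes gave 281 such genes, and the other 2 ways of pairing the libraries gave 216 and 270, so that chance could account for most. No minimum level was set beforehand. At an FPKM of at least 1 in both libraries, a level tried first, the counts were 5 for genotype and 7 and 17 for the others. The 5 were SNOR77, MT1B, AT2G36030, AT4G26290 and the chloroplast gene ATCG00650, and the 4 with an annotated length had a median length of 220.5 bases. For the 281 genes and the other pairings at any level the medians were 1498, 1605 and 1413.5 bases, against 2369 for tested genes. No biological explanation was tested for them.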
